A study of Mus musculus with 6 samples.

How the data were processed

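Total RNA from 6 tumours was treated with DNase, labelled with biotin and read on Illumina MouseWG-6 version 2.0 BeadChips, per the labels' protocols. The samples were 3 arrays titled empty vector and 3 titled uPA overexpression, and groups came from those titles alone. The deposited table of raw values holds an intensity per probe and array, neither background-subtracted nor normalised, with a detection value that rises to 1 for the brightest probes. It is thus 1 minus the usual detection p-value, and was turned round before use; the header of the deposited file calls it a p-value. The settings of scanning and bead summary are not given in the sources used here. The deposited processed values are on a log2 scale and were made with GeneSpring GX version 11.0, per the series design text. Tested on the values, their differences between arrays closely matched those of quantile-normalised log2 intensities, with the common distribution fitted to the processed values. Each probe was centred on a level that is neither the mean nor the median of these 6 arrays and stays unknown. Column medians of the processed values were 0.00227, 0.0042 and 0.00197 for empty vector 1, 2 and 3, and 0.00332, 0.00247 and 0.00288 for the arrays labelled uPA overexpression 1, 2 and 3.

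The raw table names probes by bead address and the processed table by Illumina probe ID, so rows were joined by their values. The raw log2 values were quantile-normalised to a common distribution, which was refitted to the processed values between rounds of matching. Rows, centred on the row mean, were then matched between tables as mutual nearest rows that were at least 3 times nearer than the second nearest. Of 45281 rows 45171 matched, with a median distance of 0.000576 against 0.0325 to the second nearest, and 110 did not. On shuffled and re-centred values, 45281 rows matched and 0 were wrong. Those values followed the same quantile model without added noise, so this check is lenient. The join was not checked against the maker's list of probes. Gene symbols came from the GEO platform annotation, in which 34885 probes have 1 symbol, 18 several and 10378 none. Names were taken only from probes with 1 symbol, and 34808 of these matched. Checking them by gene ID against RefSeq names of the assembly GRCm38.p6 updated 0 symbols. No coordinates are given, since no build is stated for the array.

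Background was corrected by normexp with negative control levels inferred from the detection p-values, offset 16, followed by quantile normalisation and log2 (limma 3.58.1, R 4.3.3). Probes with detection p under 0.05 on at least 3 of the 6 arrays were kept, 20434 or 45.1%, of which 3120 have no gene name. The comparison was fitted with lmFit and eBayes without covariates (4 residual and 3.35 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its probe with the highest mean over the arrays, with p adjusted again over 10826 genes. Of 229 called genes with several tested probes, 10 had a probe of opposite sign. Where a gene was above background on no array of a group, a fold is given as a lower bound. It is the mean log2 of the brighter group against the mean of, per array, the higher of the lowest detected signal and the probe's own.

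Before the data were examined, 37 gene lists were fixed, 20 of pathways and 17 of cell types, with 809 entries of which 731 are on the array. They were tested by camera with a preset correlation of 0.01 where at least 5 genes were measured, adjusted over all lists. The rule for named genes was also fixed then. It took Plau, Plaur, Plat and Serpinb2, an item not reported here, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 4 members with the smallest p of each list called or discussed. Symbols that are clone or predicted names were skipped among the largest changes. Alternatives were no background correction, offset 50, scaling to the 75th percentile, no filter and a filter on all 6 arrays, the deposited processed values, a replicate block, array weights, a trended and robust variance prior, the mean of all probes of a gene, an ordinary test, an estimated correlation and fry in the list test, and each array left out. The methods given to GEO do not name their test.

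The fit was tested on 20 simulated data sets of 10826 genes with 200 genes changed. Values were drawn from a normal distribution with each probe's mean and its variance after limma had moved it toward the common variance. Of genes changed by a fold of 2, 93.2% were recovered, and of those changed by a fold of 3, 98.6%, with 4.6% false among calls and 0 in the wrong direction. A list shifted by 0.5 on the log2 scale was called in 20 of 20 data sets. The simulation assumes independent genes, normal spread and these evened variances, without outlying arrays. It is thus kinder to the fit than the real arrays may be. Value matching used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.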

Results

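Gene expression was measured in tumours grown from 4T1 cells, a mouse mammary carcinoma line derived from the BALB/c strain. By their labels the cells carried a lentivirus for mouse urokinase-type plasminogen activator (uPA), the serine protease that turns plasminogen into plasmin, or the empty virus. They were placed in the mammary fat pad of BALB/c mice and the tumours were collected on day 7. There were 3 empty vector arrays and 3 arrays labelled uPA overexpression, each read on an Illumina mouse expression BeadChip. A probe signal was detected above background for 43.6% to 46.1% of the 45281 probes per array, and mean raw intensity ran from 415.7 to 460.8. The design text gives 3 tumours per group, but the labels do not say that each came from its own mouse. The limma p-values of single genes thus measure only the spread between these tumours, which may be less than that between mice. The number of arrays limits the precision.

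Plau, the gene that encodes uPA, was lower in the tumours labelled uPA overexpression, which is against their label. Its probe (ILMN_2629582) read 12.94 ± 0.23 (SD, n = 3) in log2 intensity in the empty vector tumours and 12.14 ± 0.18 (SD, n = 3) in the tumours labelled uPA overexpression. It thus fell by 0.80 on the log2 scale (SE 0.154, adjusted p = 0.0326 by limma), and the groups did not overlap. Every direction below is that of the labels, and the label is not borne out by this probe. Plau has 1 named probe, and where it lies in the transcript is not given in the sources used here, so whether it reads the transduced copy is open. Leaving out any single array ended the call: adjusted p was 0.104, 0.0515 and 0.0592 without empty vector 1, 2 and 3, and 0.109, 0.0601 and 0.0932 without the arrays labelled uPA overexpression 1, 2 and 3.

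Other members of the plasminogen activation system showed no called difference. Plaur, the uPA receptor, differed by -0.01 (SE 0.102, adjusted p = 0.965). Plat, which encodes tissue plasminogen activator, differed by -0.46 (SE 0.174, adjusted p = 0.187), and Serpinb2, an inhibitor of both activators, by -0.84 (SE 0.355, adjusted p = 0.228). Serpinb2 was above background on 3 empty vector arrays and 1 of the others. Of the 11 measured genes of this list 1, Plau, fell, as it did when adjusted over the list alone, and the list had a median of -0.11 and was not called (adjusted p = 0.115).

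The comparison asks which genes differ between the tumours labelled uPA overexpression and the empty vector tumours. Of 10826 genes tested, 250 rose and 336 fell in the tumours labelled uPA overexpression (limma, adjusted p under 0.05), and the groups did not overlap for any of these 586 genes. Non-overlap alone was seen for 29.7% of tested genes, where chance gives 10% for 3 against 3. Among probes, 315 rose and 415 fell of 20434 tested. At the thresholds the study states, a fold above 1.5 and an unadjusted p under 0.05, 343 genes were higher and 473 lower. The number of called genes was 54 without empty vector 1, 70 without empty vector 3, and 34, 332 and 87 without the arrays labelled uPA overexpression 1, 2 and 3. Without the same 5 arrays in turn the called probes numbered 37, 0, 21, 421 and 2. A replicate block left 77 called genes and 2 called probes. An ordinary test without shared variance called 0 genes after Benjamini-Hochberg adjustment.

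Of the 8 largest rises, 5 were in genes of mast cell proteases. Tpsab1 and Tpsb2, the mast cell tryptases, rose by 2.31 (SE 0.282) and 2.08 (SE 0.154) on the log2 scale, with adjusted p of 0.0133 and 0.00725. The carboxypeptidase gene Cpa3 rose by 1.87 (SE 0.212) and the chymase genes Mcpt4 and Cma1 by 1.84 (SE 0.211) and 1.79 (SE 0.240). The other genes of the top 8 were Angptl7 (2.14, SE 0.389), the ficolin gene Fcna (1.94, SE 0.232) and the scavenger receptor gene Fcrls (1.82, SE 0.230). Another probe of Angptl7 gave 0.94. Of these 8 genes, all but Tpsb2 lost their call when at least 1 single array was left out. Adjusted p by limma was then 0.078 to 0.094 for Angptl7 and 0.0500 to 0.0599 for the others. Near-identical sequences, as between Tpsab1 and Tpsb2, can share a probe signal, so the members of such pairs are uncertain singly.

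The 8 largest falls included 3 protease genes, Mmp10, Mmp13 and Prss12. Mmp10 and Mmp13, which encode a stromelysin and a collagenase, changed by -3.09 (SE 0.580, adjusted p = 0.0300) and -2.33 (SE 0.411, adjusted p = 0.0257) on the log2 scale, with other Mmp13 probes at -1.33 and -1.66 (the latter not called, adjusted p = 0.208). Itgb6, an integrin subunit of epithelia, fell by 2.18 (SE 0.251), with other probes at -1.99 and -0.81 (the latter not called, adjusted p = 0.189), and Lamb3, a chain of epithelial laminin, fell by 2.03 (SE 0.311). Prr9 fell by 3.01 (SE 0.199) and Slc13a2, a dicarboxylate transporter gene, fell by 2.50 (SE 0.212). These genes were above background on 1 and 2 of the 3 arrays labelled uPA overexpression. Mab21l4 fell by 2.39 (SE 0.314), and Prss12, which encodes the protease neurotrypsin, fell by 2.05 (SE 0.284). Mmp10 and Mmp13 lost their calls without empty vector 1 or 3 or the array labelled uPA overexpression 1 or 3 (adjusted p from 0.0978 to 0.102 for Mmp10 and from 0.0612 to 0.0911 for Mmp13), without a filter (0.0609 and 0.0504), with a trended prior (0.0757 and 0.0620) and with a replicate block (0.0900 and 0.0657). The rule's fixed genes, largest changes and members of called lists made 75 genes other than Plau, of which 60 had a call. Of these 60, the number that lost it in an unchanged direction was 42, 8 and 40 without empty vector 1, 2 and 3, 46, 12 and 36 without the arrays labelled uPA overexpression 1, 2 and 3, and 37 with a replicate block. It was 8 without a filter (Angptl7, Mmp10, Mmp13, Mmp9, Adamts4, Lox, Il6 and Itga5) and 4 with a trended prior (Mmp10, Mmp13, Mmp9 and Cxcl2).

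**Figure D1:**
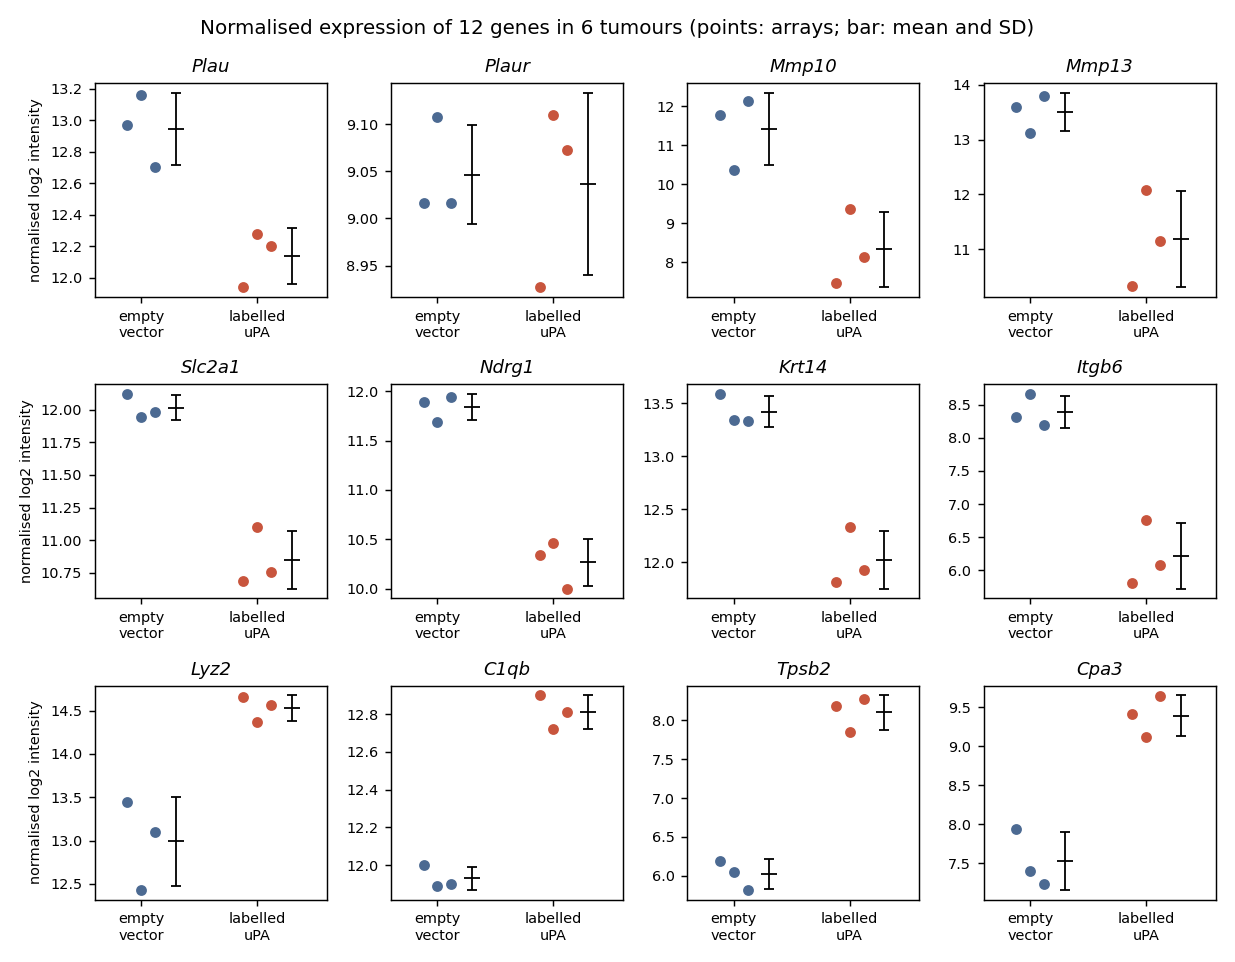
Normalised log2 intensity (vertical axes) of 12 genes in 3 empty vector arrays and 3 arrays labelled uPA overexpression; each point is an array, and the bar shows the group mean with its SD. Plau, at 12.94 and 12.14, lies lower in the group labelled uPA overexpression, Plaur overlaps, Tpsb2 and Cpa3 lie higher and Mmp10 lower.

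Gene lists fixed before the data were examined were then compared. Of 37 lists, 33 had at least 5 measured genes, and camera with a preset correlation called 5 higher and 11 lower. With an estimated correlation 0 lists were called, the smallest adjusted p being 0.149, while fry, which does not set a list against other genes, called 14. Each called list below is therefore given with its counts of genes and with its p at an estimated correlation. Some genes belong to several lists, so the lists are not independent of each other. Camera with a preset correlation takes its precision from genes, so its p-values do not measure the spread between tumours. Other splits of the arrays into 3 and 3 called 5 to 19 lists, against 16 in the real split.

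Macrophage and mast cell markers were higher in the tumours labelled uPA overexpression. Of 18 measured macrophage and monocyte genes 11 rose and 0 fell, and 14 rose when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 9.65e-11, adjusted p = 0.149 with an estimated correlation). Itgam, an integrin of myeloid cells, rose by 0.90 (SE 0.101), C1qb, a chain of complement C1q, by 0.88 (SE 0.102) and Fcgr1, an Fc receptor gene, by 1.12 (SE 0.143). Lyz1, which entered the list only through the older symbol Lyz, rose by 0.98 (SE 0.137), but another of its probes gave 0.12 (SE 0.288). Of 9 measured mast cell and basophil genes 5 rose and 0 fell, the same counts when adjusted over the list alone, with a median of 1.27, or 0.43 without a filter and 0.84 in the deposited values (camera adjusted p = 1.43e-04, adjusted p = 0.223 with an estimated correlation). Of 5 measured NK and cytotoxic cell genes, with a median of 0.39, 1 rose, Nkg7 by 0.90 (SE 0.143), and 2 when adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.295 with an estimated correlation). That median is the value of Klrb1c, which was above background on 0 empty vector arrays and at least 1.13-fold higher in the others, so it is not an exact size. The NK call was lost without empty vector 2 (adjusted p = 0.0509), without the array labelled uPA overexpression 1 (0.0564), without both (0.0803) and with array weights (0.0665), and the median was 0.17 without background correction and in the deposited values, 0.19 with offset 50 and 0.11 without a filter.

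Epithelial markers were lower. Of 16 measured mammary epithelium genes 0 rose and 7 fell, and 8 fell when adjusted over the list alone, with a median of -0.75, or -0.28 without a filter, -0.47 without background correction and -0.46 in the deposited values (camera adjusted p = 4.47e-07, adjusted p = 0.223 with an estimated correlation). Krt14, a keratin of basal epithelium, fell by 1.40 (SE 0.160), Krt7 fell by 1.06 (SE 0.151), the splicing regulator Esrp1 fell by 1.26 (SE 0.151) and the tight junction gene Cldn3 fell by 0.94 (SE 0.124). Krt8 and Krt18, the simple epithelial keratins, differed by -0.21 and -0.27 and did not pass the test. They were named after their values were seen.

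Genes of hypoxia and glycolysis were lower together. Of 23 measured members 22 lay below 0 and 8 fell, with 19 falling when adjusted over the list alone and a median of -0.49 (camera adjusted p = 2.45e-11, adjusted p = 0.223 with an estimated correlation). Ndrg1, induced by low oxygen, fell by 1.57 (SE 0.147), the collagen prolyl hydroxylase gene P4ha2 fell by 1.15 (SE 0.121), the glucose transporter gene Slc2a1 fell by 1.16 (SE 0.137) and the glycolytic gene Pgk1 fell by 0.72 (SE 0.0967). Macrophage markers were higher in the same tumours, with their median of 0.75. Oxidative phosphorylation genes had a median of 0.13 over 29 measured members, with 0 that rose or fell, also when adjusted over the list alone; of these Cox5b differed by 0.24 (SE 0.0918) (camera adjusted p = 0.0195, adjusted p = 0.223 with an estimated correlation). That call was lost with scaling to the 75th percentile (adjusted p = 0.0888), with the mean of all probes of a gene (0.0535) and without empty vector 2 and the array labelled uPA overexpression 1 together (0.0632).

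The lists of metalloproteinases, collagens and basement membrane were lower. Among 21 measured metalloproteinases, related proteases and their inhibitors 0 rose and 5 fell, 9 when adjusted over the list alone, with a median of -0.56, or -0.26 without a filter and -0.37 with array weights (camera adjusted p = 1.23e-04, adjusted p = 0.301 with an estimated correlation). Beside Mmp10 and Mmp13, Mmp3 fell by 1.25 (SE 0.206) and the aggrecanase gene Adamts4 fell by 0.83 (SE 0.164). Of 26 collagens and matrix glycoproteins 4 fell and 0 rose, and 11 fell and 1 rose when adjusted over the list alone, with a median of -0.41, or -0.27 without the array labelled uPA overexpression 1 (camera adjusted p = 1.26e-04, adjusted p = 0.451 with an estimated correlation, 0.0934 by fry). The lysyl oxidase gene Lox fell by 1.04 (SE 0.207), Col5a2 fell by 0.84 (SE 0.161), Fbln2 fell by 0.71 (SE 0.116) and Col8a1 fell by 0.69 (SE 0.129). Of 14 basement membrane genes 2 fell, Lamb3 and Agrn (-0.49, SE 0.107), the same 2 when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0163, adjusted p = 0.295 with an estimated correlation). Fibroblast markers had a median of -0.30 over 15 genes and were not called (adjusted p = 0.252).

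The lists of immediate early genes, TGF-beta targets and epithelial-mesenchymal transition were lower. Of 18 immediate early genes, which respond within minutes to growth factors and stress, 9 fell and 0 rose, 10 when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 1.47e-05, adjusted p = 0.149 with an estimated correlation). Junb, also a member of the TGF-beta targets, fell by 1.07 (SE 0.165), Fos fell by 0.84 (SE 0.155), Egr1 fell by 0.74 (SE 0.129) and Fosb fell by 0.74 (SE 0.111). Of 17 TGF-beta targets 5 fell, 7 when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 4.7e-05, adjusted p = 0.223 with an estimated correlation). Pmepa1 and Bhlhe40 each fell by 0.90 (SE 0.103 and 0.135). Tgfb2, which encodes a TGF-beta ligand, fell by 0.78 (SE 0.135). The list holds ligand genes beside targets, so its counts and median are not of targets alone. In the list of epithelial-mesenchymal transition 4 of 19 genes fell, 7 when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00419, adjusted p = 0.295 with an estimated correlation). Its members Tagln, an actin-binding protein gene, fell by 1.44 (SE 0.195), Prrx1 fell by 0.99 (SE 0.156), Itga5 fell by 0.99 (SE 0.189) and Foxc2 fell by 0.66 (SE 0.136). Of the 3 other Prrx1 probes 1 was called, at -1.12, and 2 were not, at -0.51 and -0.43, and the mean of its probes was not called (-0.76, adjusted p = 0.0572).

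The lists of cytokines, neutrophil genes and angiogenic factors were lower, with called members in both directions. Of 25 cytokines and chemokines 4 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone, with a median of -0.40, or -0.25 without background correction and in the deposited values (camera adjusted p = 0.0023, adjusted p = 0.295 with an estimated correlation). Cxcl1, a neutrophil attractant, fell by 1.40 (SE 0.151), Csf2 fell by 1.29 (SE 0.225) and Il6, above background on 2 of the 3 arrays labelled uPA overexpression, fell by 1.00 (SE 0.192). Cxcl2 was not above background on any array labelled uPA overexpression and was at least 1.26-fold lower there (adjusted p = 0.0442) with the background correction used. The Cxcl2 call was lost without background correction (-0.25, adjusted p = 0.0932), with offset 50 (-0.27, 0.104), in the deposited values (-0.25, 0.0938), differences smaller than that bound, with a trended prior (0.0606) and without any 1 array (0.0707 to 0.142). Of 11 neutrophil genes 3 fell and 1 rose, and 5 fell and 1 rose when adjusted over the list alone, with a median of -0.51, or -0.17 without a filter (camera adjusted p = 0.0173, adjusted p = 0.295 with an estimated correlation, 0.0866 by fry). S100a9 fell by 1.18 (SE 0.214) and the decoy receptor gene Il1r2 fell by 1.14 (SE 0.182). Mmp9, also among the 5 falls of the metalloproteinase list, fell by 1.73 (SE 0.346), while the formyl peptide receptor gene Fpr2 rose by 1.12 (SE 0.156). Of 23 angiogenic factors and receptors 4 fell and 1 rose, and 8 fell and 2 rose when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.0195, adjusted p = 0.313 with an estimated correlation). The placental growth factor gene Pgf fell by 1.54 (SE 0.148), Jag1, a Notch ligand gene, fell by 0.99 (SE 0.137) and Pdgfb fell by 0.89 (SE 0.166), while Angpt1, a Tek ligand above background on 2 of the 3 empty vector arrays, rose by 1.71 (SE 0.194). The neutrophil call was lost without the array labelled uPA overexpression 3 (adjusted p = 0.123).

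Cell cycle genes had a median of 0.16 over 29 members (0.07 without empty vector 3, 0.08 without the array labelled uPA overexpression 3 and 0.09 with scaling to the 75th percentile), of which 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.581 with an estimated correlation, 0.270 by fry). This was Ccne2, a cyclin of the start of DNA replication, at 0.69 (SE 0.135). The next genes by p were Mcm3 (0.52, adjusted p = 0.0762), Ccna2 (-0.52, adjusted p = 0.143) and Aurkb (0.36, adjusted p = 0.178). The call was lost without the array labelled uPA overexpression 3 (adjusted p = 0.231).

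Lists of other cell types and processes were not called. Endothelial genes had a median of 0.02 over 18 measured members, with 0 that rose or fell, also when adjusted over the list alone (adjusted p = 0.702), and T cell genes 0.15 over 14 (adjusted p = 0.264). Pericyte and smooth muscle genes had a median of -0.05 over 11, of which 1, Pdgfrb, fell by 0.80 (SE 0.135) (adjusted p = 0.338). Dendritic cell genes had a median of -0.05 (adjusted p = 0.839) and adipocyte genes -0.12 (adjusted p = 0.691). Of 28 genes of the interferon-gamma response and antigen presentation 1 rose, H2-DMa by 0.62 (SE 0.117), and the list had a median of 0.08 (adjusted p = 0.125). Type I interferon genes had a median of -0.08 (adjusted p = 0.252), ribosomal protein genes -0.03 (adjusted p = 0.233), cholesterol synthesis genes -0.01 (adjusted p = 0.445) and apoptosis and p53 target genes -0.06 (adjusted p = 0.445). In those last lists Sc5d, of cholesterol synthesis, fell by 0.53 (SE 0.118) and Sesn1, a p53 target, rose by 0.92 (SE 0.190). Adjusted over the list alone, 3 pericyte genes fell and 1 rose, and 1 fibroblast gene and 1 T cell gene fell, in both lists Thy1, at -0.56 (adjusted p = 0.0501 over all genes).

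**Figure D2:**
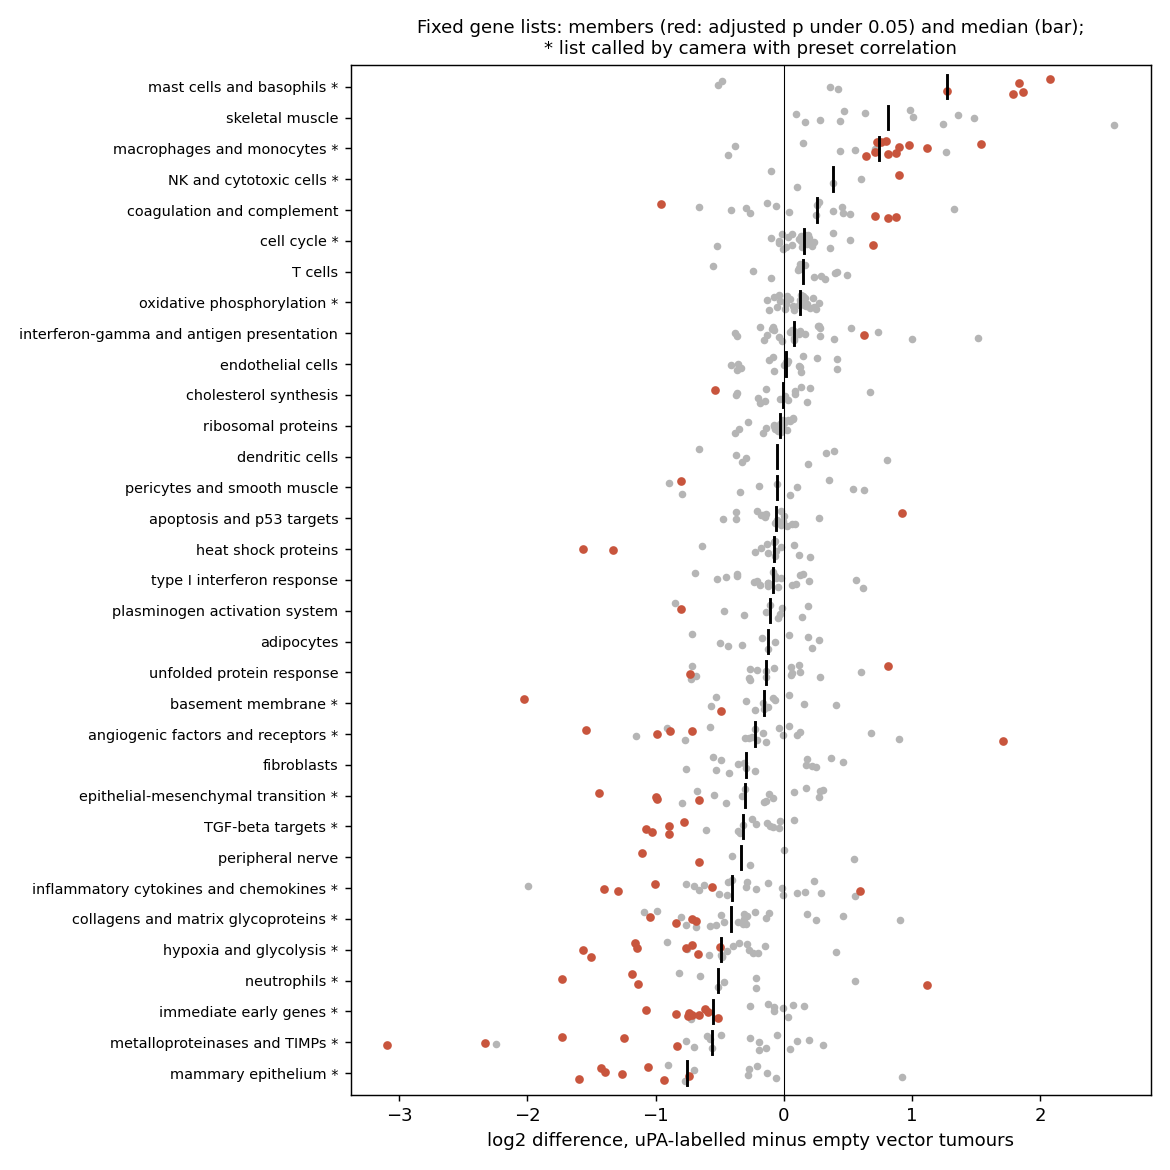
Log2 difference of each measured member (points, horizontal axis, tumours labelled uPA overexpression minus empty vector) in 33 fixed lists; red points have an adjusted p under 0.05, the vertical bar is the list median, and an asterisk marks lists called with a preset correlation. Medians run from 1.27 in mast cell and basophil genes to -0.75 in mammary epithelium genes.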

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

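The run that leaves out empty vector 2 and the array labelled uPA overexpression 1 together was chosen after seeing the data. So were the macrophage list without genes shared with another list and the mammary epithelium list without keratins. Both of these lists kept their direction and their call by camera with a preset correlation. All other alternatives were planned. The number of called genes (586) was 1073 with array weights and 219 without that pair of arrays, and ran from 34 (without the array labelled uPA overexpression 1) to 609 (without empty vector 2) when each array was left out. Called probes (730) numbered 452 without a filter, 1508 with array weights, 1127 with a trended and robust prior, 266 without the pair of arrays, and from 0 (without empty vector 3) to 798 (without empty vector 2) when each array was left out. Genes past the stated thresholds (816) numbered 469 without background correction and 439 in the deposited processed values, and from 787 to 893 when each array was left out. An ordinary test without shared variance gave 677 at those thresholds and 0 after Benjamini-Hochberg adjustment, beside 2310 genes at unadjusted p under 0.05 by limma. Plau stayed lower in each alternative run: -0.59 (adjusted p = 0.0884) without the pair of arrays and from -0.92 to -0.69 when each array was left out, with adjusted p from 0.0515 to 0.109. Called lists (16) fell to 0 with an estimated correlation and numbered 16 to 19 when each array was left out. Of these 16 lists 9 had a median that moved by over 1.5 times, with 0 changes of sign. Without a filter, mammary epithelium (-0.75) went to -0.28, mast cells (1.27) to 0.43, metalloproteinases (-0.56) to -0.26, neutrophils (-0.51) to -0.17 and NK cells (0.39) to 0.11. Without background correction mammary epithelium went to -0.47, cytokines (-0.40) to -0.25 and NK cells to 0.17; in the deposited values these were -0.46, -0.25 and 0.17, and mast cells 0.84. Offset 50 gave 0.19 for NK cells and array weights -0.37 for metalloproteinases. Scaling to the 75th percentile gave 0.0924 for cell cycle (0.16) and 0.0667 for oxidative phosphorylation (0.13), which was 0.0839 with the mean of all probes. Leaving out 1 array took cell cycle to between 0.0652 and 0.172, and collagens (-0.41) to -0.27 without the array labelled uPA overexpression 1. Without the pair of arrays metalloproteinases were at -0.29, collagens at -0.26 and NK cells at 0.17. With fewer arrays the test has fewer degrees of freedom; for the other changes the cause was not tested. The design text gives no pairing of arrays by replicate number. Correlations of deviations were -0.186, -0.264 and 0.0727 for numbers 1, 2 and 3, against up to 0.322 between different numbers. Deviations sum to 0 within each group, so these correlations cannot show that pairing is absent. Skeletal muscle genes were highest in number 3 of both groups (1.17 and 2.68 relative to the empty vector mean). With a replicate block, 77 genes and 2 probes were called, and Plau differed by -0.80 (limma adjusted p = 0.0809). Plaur changed sign, at 0.0293 with array weights, 0.0754 without the pair of arrays, and from -0.0462 (without the array labelled uPA overexpression 2) to 0.0452 (without that labelled 1) when each array was left out. Lyz1 ran from -0.0266 (without the array labelled uPA overexpression 1) to 1.09 (without empty vector 1); in the former another of its probes had the highest mean and the reported probe gave 0.96. Scaling to the 75th percentile moved the median of all genes to -0.0474. A slide block was not run, as the tables name no slide. Signal over background limits Prr9, Slc13a2, Serpinb2, Il6, Angpt1, Klrb1c and Cxcl2.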

Other observations

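All tests of explanations and the symbol families here were chosen after the results were seen, as were the genes named here outside the fixed rule; the gene lists were fixed before. Of 168 families of shared symbol stem, Tlr, of Toll-like receptor genes, had a median of 0.61 over 9 genes, of which 3 rose and 1 fell in the tumours labelled uPA overexpression (camera adjusted p = 0.00413, adjusted p = 0.808 with an estimated correlation), and 8 of the 9 lay above 0 under each scaling tried. Tlr7 rose by 1.05, Tlr1 by 0.86 and Tlr13 by 0.77, while Tlr3 fell by 0.67. The macrophage and monocyte list, with its median of 0.75, was higher in the same tumours, and whether the Tlr and Clec genes move apart from it was not tested. Of 17 genes of the stem Clec 4 rose and 0 fell, among them Clec4a1 by 1.34 and Clec4a3 by 1.26, and the family was not called (median 0.13, adjusted p = 0.152). Collagen genes (stem Col) had a median of -0.36 over 25 genes, of which 6 fell and 0 rose (camera adjusted p = 0.00235, adjusted p = 0.808 with an estimated correlation). Of 8 Wnt ligand genes 3 fell, Wnt7a at -1.50, Wnt10a at -1.33 and Wnt5a at -1.27, and this family was not called either (median -0.41, adjusted p = 0.117). In the coagulation and complement list, with a median of 0.26 that was not called (adjusted p = 0.108), C1qa, C1qb and C1qc, also in the macrophage list, rose by 0.81, 0.88 and 0.71. Serping1, the C1 inhibitor gene, fell by 0.96, and over the list alone 4 rose and 1 fell.

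The inducible heat shock genes Hspa1a and Hspa1b changed by -1.33 (adjusted p = 0.0429) and -1.57 (adjusted p = 0.0471), while their list had a median of -0.08 and was not called (adjusted p = 0.129). Another probe of each gave -1.14 and -0.94, and neither was called. Hspa1a read 6.78, 5.64 and 6.67 in empty vector 1, 2 and 3. The unfolded protein response list had a median of -0.14 (adjusted p = 0.252), with Sdf2l1 rising by 0.81 and Ddit3 falling, at -0.73. In the peripheral nerve list (median -0.33, adjusted p = 0.0606) Ncam1 fell by 1.10, but another of its probes gave -0.28. Skeletal muscle genes had a median of 0.81 over 12 genes with 0 called (adjusted p = 0.0606); relative to the empty vector mean, the list median was 1.17 in empty vector 3 and 2.68 in the array labelled uPA overexpression 3, against -0.70 to 0.10 in the other arrays. The lists with fewer than 5 measured genes were not tested: medians were 1.12 for lymphatic endothelium, 0.64 for B and plasma cells, -0.32 for erythroid cells and 0.51 for skin keratinocytes. In single arrays labelled uPA overexpression 1, 2 and 3, relative to the empty vector mean, these were 1.36, 0.00 and 0.98 for lymphatic endothelium and 0.89, 0.84 and 0.17 for B and plasma cells. They were -0.52, -0.71 and 0.35 for erythroid cells, and 1.78, -0.18 and -0.07 for keratinocytes, so the keratinocyte value rests on 1 array. Empty vector 2 stood apart on the second principal component, at -31.6 against 19.1 and 23.1 in the other empty vector arrays. The array labelled uPA overexpression 1 lay on the same side, at -16.9, against 7.95 and -1.67 for those labelled 2 and 3.

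Plau was lower in the tumours labelled uPA overexpression (-0.80). A single wrongly labelled array, or an exchange of 1 array for 1, is argued against if the 2 kinds of tumour differ in expression: the 15 groupings with 1 array moved or 1 exchanged called 0 genes, against 586, and gave Plau at -0.78 to 0.01, while the first principal component of all tested probes parted the groups (-35.5 to -17.6 and 19.3 to 26.7). An exchange of the labels of the whole groups cannot be told apart from a true fall, because the difference of -0.80 is itself what raised the question. Equally open is that the probe may read the native transcript and not the transduced copy, as Plau has 1 named probe and no sequence of it was analysed here. A response of the native gene to the transduced one was not tested.

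Macrophage and mast cell markers were higher and epithelial markers lower in the tumours labelled uPA overexpression. A lower share of tumour cells should raise every other cell type alike. The median of 27 macrophage and mast cell genes was 0.76. That of 57 endothelial, fibroblast, pericyte and T cell genes was 0.05, a gap of 0.71 (95% bootstrap interval over genes 0.479 to 0.960). The interval treats genes as independent and holds no spread between tumours. Both sets were chosen after the list medians were seen, so a gap above 0 was built into that choice. Cell type lists left out went both ways, such as NK cells at 0.39, skeletal muscle at 0.81 and neutrophils at -0.51. In single empty vector arrays, relative to their mean, medians ran from -0.256 to 0.331 for fibroblasts, -0.226 to 0.300 for T cells and -0.030 to 0.078 for macrophages. The gap therefore does not decide against a lower share alone, and 4T1 cells may also express some of the 57 genes. With a preset correlation the macrophage, mast cell and epithelial lists stayed called. The largest camera adjusted p was 1.54e-04 over alternatives of background correction, filter and normalisation, and 0.00205 without any 1 array. That test takes its precision from genes, and other splits of the arrays into 3 and 3 called 5 to 19 lists, so staying called decides little. Over all refits the medians ran from 0.67 to 0.82 for macrophages, 0.43 to 1.52 for mast cells and -0.85 to -0.28 for epithelium. No alternative tried and no single array thus set the direction of these medians. The same held for all 16 called lists, so it does not set these lists apart. With an estimated correlation these lists were not called (adjusted p = 0.149 for macrophages and 0.223 for the others), and without a filter the epithelial median was -0.28 and the mast cell median 0.43, against -0.75 and 1.27. A change in macrophages and mast cells themselves, tied to the label, may account for their rise but was not tested. How many genes of either set 4T1 cells also express is not known here.

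The arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 730 probes and 586 genes, against a highest of 0 in the other splits for each, so 1 of the 10 splits gave as many. For genes past the stated thresholds the real split gave 816 and the highest other 220, again 1 of 10. For gene lists it gave 16 and the highest other 19, so 2 of the 10 splits gave as many.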
